A study of Mus musculus with 15 samples.

How the data were processed

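Expression was measured in 15 samples, 1 array each, of LSK cells from the bone marrow of C57BL6 mice. Per the labels' protocols the cells were transduced with a retrovirus that carries Cre and GFP, GFP-positive cells were sorted, total RNA of more than 10000 cells per sample was isolated with a micro column kit, amplified with Nugen Ovation V2 and labelled with biotin. Per the labels the genotypes at Apc were wt/wt (6 samples), 15lox/15lox (3), 15lox/1572T (3) and 15lox/1638N (3). The labels name no batch and do not say whether the replicates of a group came from separate animals.

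The deposited values are log2 probe set summaries, per the range and quartiles of the values, since no file header names the unit. The submitters' processing notes name RMA and the build mm9 without giving either a role or a version. Settings, background correction and any quality filter on arrays are not given in the sources used here. Quartiles were nearly equal on all 15 arrays and set none of them apart. The values of wild-type arrays 1 to 3 look shifted, probe set by probe set, so that their mean equals the mean of wild-type arrays 4 to 6, which is read from the values and is stated in none of the sources used here. The table held 45101 probe sets, 15 arrays, 0 missing values and 0 columns of other series. The platform's annotation table paired 34958 probe sets with 1 gene symbol and 932 with several, and did not list 9211. No symbol needed an update through its Entrez identifier in the table for assembly GRCm38.p6, which was used for names only; no coordinates are given.

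Probe sets with exactly 1 symbol were used, 1 per gene, that with the highest mean over all 15 arrays, which left 18194 genes; 9012 of them had over 1 probe set. There was no filter on level and no further normalization. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options) on all 15 arrays, with 11 residual degrees of freedom. The contrasts were each mutant genotype against wild type and each pair of mutant genotypes, along with a moderated F test over the 4 groups and a regression on scores for the order wild type, 15lox/1572T, 15lox/1638N, 15lox/15lox. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each contrast, and the threshold was an adjusted p under 0.05. Probe sets of Apc were also tested singly over all 45101. Values are given as log2 fold change with its SE, or as group mean with SD.

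There were 27 gene lists, written from background knowledge, plus controls for sex and housekeeping. They were tested with camera at the preset correlation of 0.01 between genes, and p was adjusted over the 81 tests of 27 lists in 3 contrasts. Members past the threshold were counted with p adjusted over all genes, and again with p adjusted over the list alone. The same lists between mutant genotypes, a list of plasmacytoid dendritic cell markers and the comparison of the wild-type sets of 3 were added after the data were seen. The tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

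Named genes were chosen as follows. In each contrast with wild type, the 8 genes with the highest and the 8 with the lowest log2 fold change were taken among those past the threshold whose mutant arrays all lay outside the range of the wild-type arrays, without placeholder symbols and sex-linked genes. Apc, Ctnnb1, Axin2, Lef1, Nkd1, Ccnd1, Myc and Tcf7, where measured, were taken whatever their values. From each list past its test, or with at least 2 members past the threshold, the 4 members of lowest p were taken, and between mutant genotypes and for the trend 5 genes in each direction. Outside this rule, and chosen after their values were seen, are further members of the Wnt target list (Bmp4, Lgr5 and those given between mutant genotypes), and Irf4 and Il7r in 15lox/1638N.

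Correlations of log2 fold changes were compared with 100 simulations of unchanged groups against the same controls and with splits of the wild-type arrays. Shared genes and signs were compared with 20 simulated sets, a test added after the data were seen. Sex was read from Xist and Y-linked genes. Alternatives covered filters on low levels, normalization, eBayes options, array weights, fits on fewer arrays, the replicate number as a block, sex as a covariate, other thresholds, all probe sets or their mean, other list tests, the allele order, and each array left out in turn. After the data were seen, fits with wild-type arrays 1 to 3 as a group of their own, and with wild-type arrays 4 to 6 only and sex as a covariate, were added.

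The method was tested on simulated data of the size of the 15lox/15lox comparison. It found 68.7% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, with 11 false calls among 18194 genes. With wild-type arrays 1 to 3 shifted as in the data these were 80.6%, 94.0% and 100%, with 67 false calls. The changed genes numbered only 67, 67 and 66 in that order, so false calls were a large part of all calls there. With the shift, the threshold of adjusted p under 0.05 did not hold the share of false calls near 0.05. Counts of genes called with all wild-type arrays may therefore hold more false calls than that threshold states. In 20 simulated sets without change the median number of genes called was 0, and 1 with the shift, with at most 8. These simulations, and those for correlations and shared genes, draw each gene independently and so hold no structure shared by the genes of an array. They can understate false calls: another split of the real 15lox/15lox and wild-type arrays called 454 genes. The spread between 3 arrays limits what can be called, and arrays have no depth in reads.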

Results

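Expression was measured on 15 arrays, 1 per sample, in blood stem and progenitor cells from the bone marrow of C57BL6 mice. The starting cells were LSK cells, a population that lacks lineage markers and carries Sca1 and Kit on its surface. They received a retrovirus encoding Cre recombinase and a green fluorescent marker ex vivo, and the marker-positive cells were sorted and grown with Flt3 ligand, thrombopoietin and stem cell factor. The 4 genotypes concern Apc, which encodes a scaffold of the complex that marks beta-catenin for degradation and so restrains Wnt signalling. There were 6 wild-type samples (wt/wt), 3 with a pair of floxed alleles (15lox/15lox), 3 with a floxed allele and the hypomorphic allele 1638N (15lox/1638N), and 3 with a floxed allele and the hypomorphic allele 1572T (15lox/1572T). The stated purpose was to examine what Wnt signals do in haematopoietic cells. Levels are log2 values, array medians ran from 6.65 to 6.84, and the number of arrays limits the precision of every value. The labels do not say whether replicates of a group were separate animals, so p-values measure only the spread between these samples. Xist and the Y-linked genes differed between arrays within every group, with 2 female-type arrays of 6 in wild type, 2 of 3 in 15lox/15lox, and 1 of 3 in each hypomorph group. Wild-type arrays 4 to 6 were all male-type, and arrays 1 to 3 look shifted onto their mean. The wild-type mean is then that of male-type arrays, while each mutant group mixes both types.

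The 6 wild-type arrays fell into a pair of sets whose values were not independent. At 96.7% of the 45101 probe sets the mean of wild-type arrays 1 to 3 lay within 0.05 of the mean of wild-type arrays 4 to 6, against 20.2% to 26.1% for the other 9 pairs among these sets and the 3 mutant groups. The SD over probe sets of the difference between the means was 0.0227 for these sets, while the other 9 ways of dividing the wild-type arrays into sets of 3 gave 0.120 to 0.201. In wild-type arrays 1 to 3 all 3 values were equal at 18.2% of probe sets, against at most 0.0177% in the other sets. Xist read 9.63 and 9.88 in wild-type arrays 1 and 2 and 3.62 in array 3, where the male-type mutant arrays read 7.71 to 7.98 and the female-type mutant arrays 13.75 to 14.02. The spread of 6 wild-type arrays is therefore understated, and the number of genes called in each comparison below is given with all 6 wild-type arrays and again with wild-type arrays 4 to 6 only. In simulated data without any change, shifting arrays 1 to 3 onto the mean of arrays 4 to 6 raised the share of genes with p under 0.05 from 5.04% to 10.1%.

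**Figure D1:**
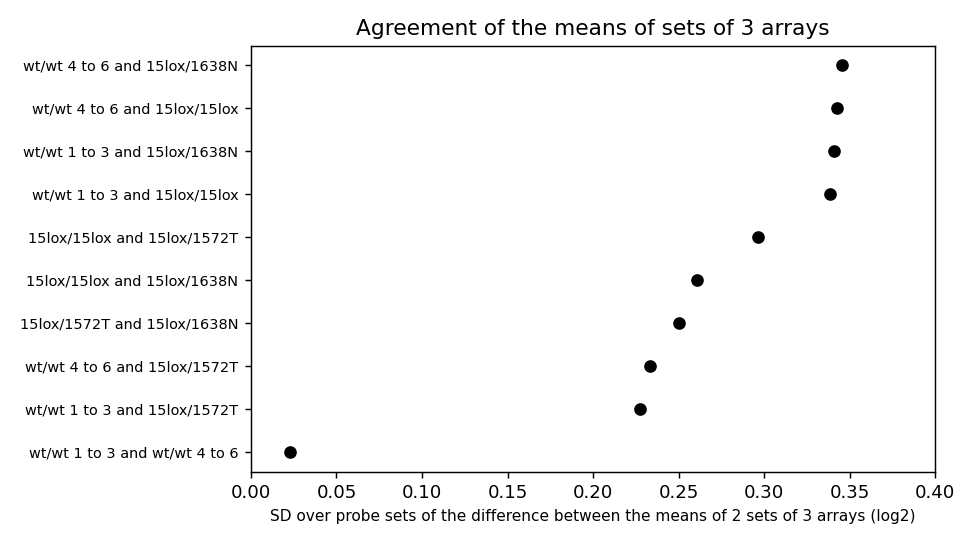
Each point is the SD over all probe sets of the difference between the mean log2 levels of 2 sets of 3 arrays, named on the vertical axis. Wild-type arrays 1 to 3 and 4 to 6 differed by 0.0227, and the other pairs by 0.228 to 0.345.

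Apc itself was read by 4 probe sets that moved in opposite directions. Probe set 1420956_at fell from 9.75 ± 0.15 in wild-type cells (SD, n = 6) to 5.79 ± 0.27 in 15lox/15lox cells (SD, n = 3), which was 15.6-fold lower (adjusted p = 6.9e-10 over all probe sets). It read 5.58, 6.10 and 5.69 on the 3 arrays of 15lox/15lox, and 9.57 to 9.93 on those of wild type. Its level was 2.30-fold lower in 15lox/1638N cells and 1.91-fold lower in 15lox/1572T cells, each below every wild-type array. Probe set 1420957_at fell by 3.90 in 15lox/15lox and by 1.31 in 15lox/1638N, and its value of -0.78 in 15lox/1572T missed the threshold (adjusted p = 0.0842). Probe set 1450056_at fell in all 3, by 1.43, 0.53 and 0.75. In 15lox/15lox 1420957_at and 1450056_at averaged 5.06 and 5.19, near percentiles 27 and 30 of all probe sets, where background adds to the signal. Their falls there may be lower bounds. Probe set 1435543_at, which has the highest mean of the 4 and stands for Apc in the counts of genes, rose by 0.77 ± 0.10 (SE) in 15lox/15lox, where it read 10.23 to 10.66 against 9.57 to 9.85 in wild type, and by 0.52 ± 0.10 in 15lox/1572T (adjusted p = 0.0252 over genes). The latter call ended without wild-type array 1, 4 or 5 or 15lox/1572T array 1, with adjusted p from 0.0533 to 0.121, and with wild-type arrays 4 to 6 only (adjusted p = 0.260). There the direction of Apc depends on the probe set: with the mean of the 4, Apc fell by 2.13 in 15lox/15lox, by 0.72 in 15lox/1638N and by 0.49 in 15lox/1572T. The position of each probe set relative to the deleted part of the gene was not used here, and a probe set outside that part checks nothing about the labels.

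**Figure D2:**
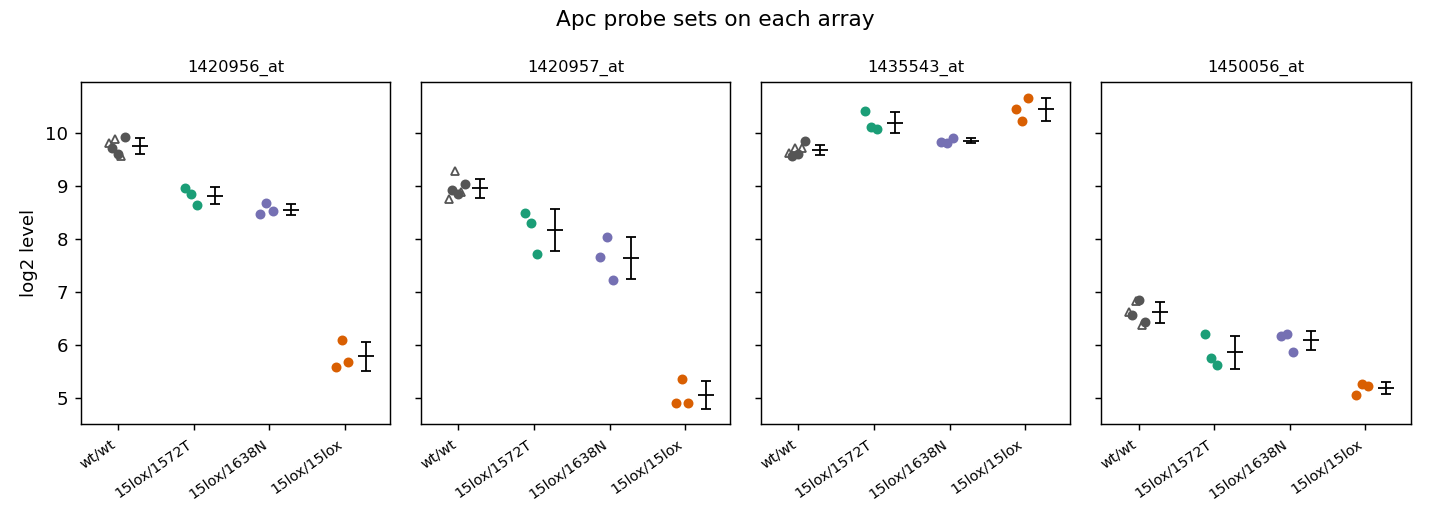
Each panel shows the log2 level of 1 of the 4 Apc probe sets on every array, by genotype; open triangles are wild-type arrays 1 to 3, filled circles all other arrays, and bars the mean with its SD. At 1420956_at the 15lox/15lox arrays lie at 5.58 to 6.10 and the wild-type arrays at 9.57 to 9.93, while at 1435543_at the 15lox/15lox arrays lie above the wild-type arrays.

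The 15lox/15lox cells were compared with wild-type cells to ask what the floxed pair of alleles did after Cre. Negative-feedback genes of the Wnt pathway were among those that rose: Axin2, a component of the beta-catenin degradation complex, went from 7.40 ± 0.38 (SD, n = 6) to 12.17 ± 0.20 (SD, n = 3), which was 27.3-fold (adjusted p = 1.3e-07). Lef1, a transcription factor that binds beta-catenin, rose 15.3-fold, and Nkd1, an inhibitor of the pathway, 5.23-fold. The increases of the genes chosen by size were larger still. Sult1a1, a sulfotransferase, rose from 5.46 ± 0.35 to 12.54 ± 0.46 or 136-fold, and Edar, a receptor of the tumour necrosis factor family, from 4.59 ± 0.15 to 11.12 ± 0.23, 92.1-fold at the probe set used. That wild-type level of Edar lies near percentile 16 of the probe set means, where background adds to the signal, so folds at this probe set are lower bounds for it alone. Over the alternative fits, which include the mean of its probe sets, the log2 fold change of Edar ran from 3.21 to 6.66, always past the threshold. The wild-type level of Sult1a1 lies near percentile 34, within the 4.81 to 5.61 that the Y-linked Uty read on female-type mutant arrays. The folds of Sult1a1 against wild type may therefore be lower bounds too. Ahsg, a plasma glycoprotein usually made by liver, rose 72.3-fold, Rasgrp1, an activator of Ras in lymphocytes, 63.8-fold, Plpp1 62.3-fold, Phlda1 35.9-fold, Efhd1 31.6-fold and Cd83 30.7-fold. Over the alternative fits the log2 fold change of Rasgrp1 ran from 3.08 to 6.27 and that of Lef1 from 2.16 to 4.43. That of Ahsg stayed within 5.73 to 6.23. On the other side Igha, an immunoglobulin heavy chain constant region, fell by 3.26 ± 0.62 (SE), Cd7 by 3.05 ± 0.50, Cracdl by 2.52 ± 0.23, Sparc by 2.29 ± 0.38 and Sdc4 by 2.19 ± 0.38. Beta-catenin's own gene Ctnnb1 did not pass the test (log2 fold change 0.13, adjusted p = 0.314), and neither did Ccnd1 (-0.20, adjusted p = 0.468) or Myc (-0.25, adjusted p = 0.732).

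In all, 1199 of 18194 genes were called in 15lox/15lox cells, 534 higher and 665 lower, and 227 of the higher and 75 of the lower changed over 2-fold. With wild-type arrays 4 to 6 only, 464 genes were called, 327 higher and 137 lower, so the share of higher genes went from 44.5% to 70.5%. Of the 16 genes chosen by size, 15 were past the threshold in that fit too; Cd74 was the exception. With sex as a covariate in that fit 260 genes were called, and Igha, Sdc4, Sparc, Ly6d, H2-Eb1, Ciita, Ighm, Ebf1, Gata3, Pmepa1, Prtn3 and the Apc probe set used were not among them. Without 15lox/15lox array 2 the count with all wild-type arrays was 598. The called genes had a median absolute log2 fold change of 0.58.

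Of 21 measured Wnt/beta-catenin target genes, 13 rose and 0 fell in 15lox/15lox cells (14 higher and 1 lower, adjusted over the list alone; 12 higher with wild-type arrays 4 to 6). The median log2 fold change of the list was 1.29, and its test gave adjusted p = 4.2e-22, or adjusted p = 0.0129 with an estimated correlation between genes. Besides Axin2, Lef1 and Nkd1, and named after its values were seen, the bone morphogenetic protein Bmp4 rose by 4.48, the surface inhibitor Apcdd1 by 3.07 and the receptor Tnfrsf19 by 2.40. The list of 32 haematopoietic stem cell genes also passed (adjusted p = 0.0432), with a median of only 0.09 and 1 member past the threshold, the angiopoietin receptor Tek, which rose by 2.22 ± 0.27 (SE); this list had adjusted p = 0.659 with an estimated correlation. The other 25 lists did not pass, with a lowest adjusted p of 0.0647. The count of 2 lists was 4 without wild-type array 2, 5 without wild-type array 5, 5 without 15lox/15lox array 1, 4 without 15lox/15lox array 3 and 1 without 15lox/1572T array 1.

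Several lists that did not pass as a whole in 15lox/15lox cells held members that changed. Of 14 dendritic cell and MHC class II genes, 4 fell and 1 rose (7 and 1 adjusted over the list alone; 2 and 1 with wild-type arrays 4 to 6). Ciita, the master regulator of MHC class II genes, fell by 1.60 and H2-Eb1 by 1.97, while Irf4 rose by 3.05 ± 0.31 (SE). Cd74, the invariant chain, fell by 2.46, a call that ended without 15lox/15lox array 1 (adjusted p = 0.0614) or array 2 (adjusted p = 0.0932). Of 14 early lymphoid progenitor genes, Ccr9 fell by 2.62, Ly6d by 2.45 and Ighm by 0.67, the last not past without 15lox/15lox array 2 (adjusted p = 0.0697), whereas the interleukin-7 receptor Il7r rose by 4.14 ± 0.44 (SE); 5 fell and 1 rose adjusted over the list alone, and 3 and 1 with wild-type arrays 4 to 6. Among 19 monocyte and macrophage markers Cd14, the lipopolysaccharide co-receptor, rose by 2.41, F13a1 by 1.66 and Ccr2 by 1.13, and the median of the list was -0.01 while its test pointed upward (3 higher and 1 lower adjusted over the list alone; 3 and 0 with wild-type arrays 4 to 6). Of 15 T cell markers 3 rose and 3 fell (3 and 3 adjusted over the list alone; 1 and 2 with wild-type arrays 4 to 6), among them Gata3 at 1.24, Cd3g at -1.27 and Lat at -0.87. The B cell factor Ebf1 fell by 1.81 and the coactivator Pou2af1 rose by 2.16. Of the Notch target genes Dtx1 fell by 1.26 and Hey2, whose wild-type level of 4.09 is lower still than that of Edar, rose by at least 0.73. The granulocyte protease Prtn3 rose by 0.37 and Anxa1 by 0.98, calls that ended with wild-type arrays 4 to 6 only (Prtn3) and with the mean of its probe sets (Anxa1), and Pmepa1, a gene induced by TGF-beta, fell by 0.86. For 6 of the 27 lists, none of them past the test, the median, mean and test differed in sign.

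**Figure D3:**
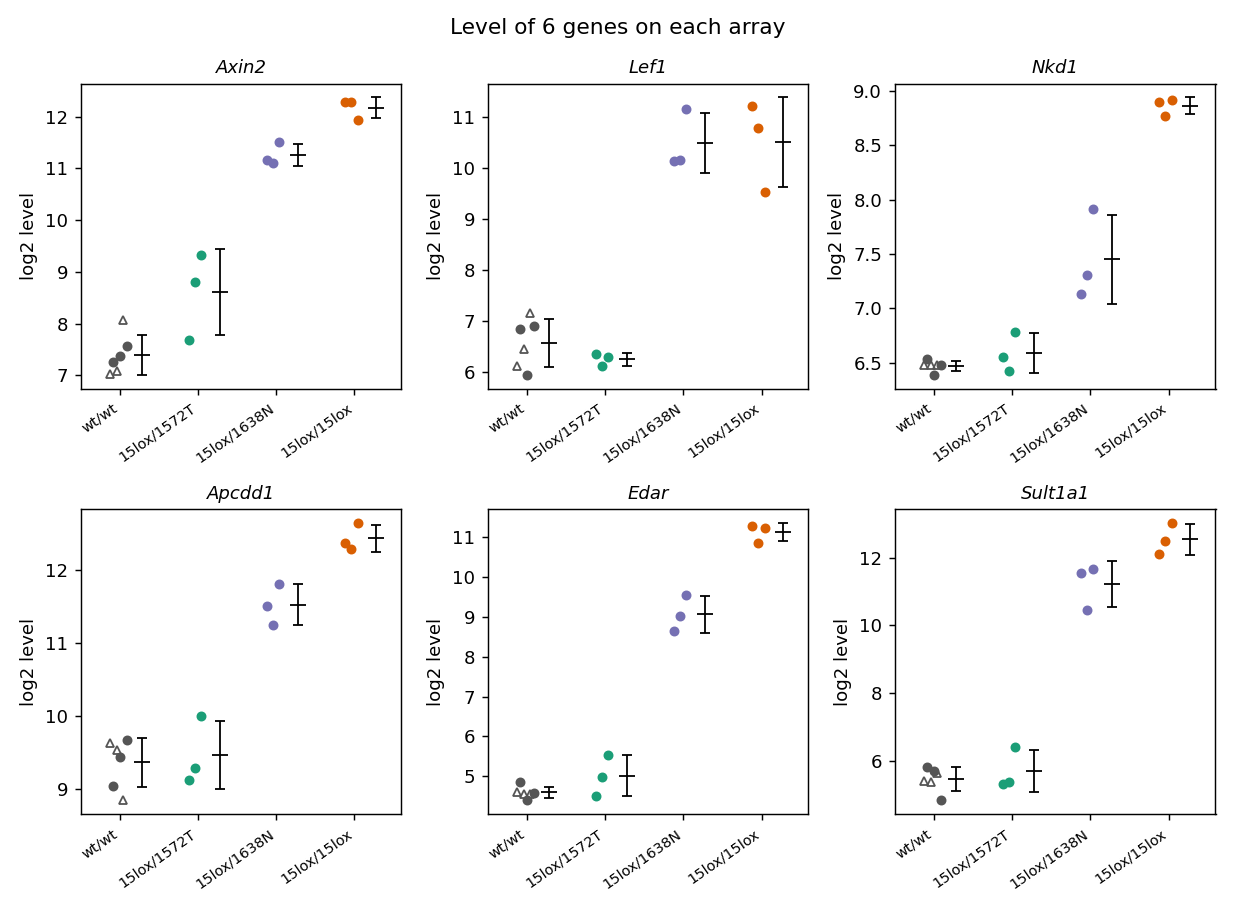
Each panel shows the log2 level of 1 gene on every array, by genotype; open triangles are wild-type arrays 1 to 3, filled circles all other arrays, and bars the mean with its SD. Axin2 averages 7.40 in wild-type and 12.17 in 15lox/15lox cells, Edar 4.59 and 11.12, and Sult1a1 5.46 and 12.54.

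In 15lox/1638N cells, which kept the hypomorphic allele 1638N, the same comparison with wild type showed Sult1a1 54.6-fold higher (11.23 ± 0.67 against 5.46 ± 0.35, SD, n = 3 and 6, adjusted p = 1.3e-07). Plpp1, a lipid phosphate phosphatase, rose 28.9-fold, Rasgrp1 25.7-fold, Edar 22.2-fold at the probe set used, Pxdc1 20.4-fold and Zcchc14 19.3-fold. Over the alternative fits the log2 fold change of Edar ran from 2.21 to 4.69 and that of Rasgrp1 from 2.11 to 5.00, always past the threshold. Pdcd1, the inhibitory receptor PD-1 of lymphocytes, rose 16.7-fold, from 6.66 ± 0.63 to 10.73 ± 0.50. Axin2 rose by 3.86 ± 0.29 (SE), Lef1 by 3.92 ± 0.35 and Nkd1 by 0.98 ± 0.13, and Cd14 by 3.52 ± 0.17. The largest decreases included Igha (-4.18 ± 0.62), Cd7 (-3.83 ± 0.50), Cd74 (-3.59 ± 0.54), H2-Aa (-3.26 ± 0.59) and H2-Eb1 (-2.86 ± 0.36). The peptide transporter Slc15a2 was 18.3-fold lower, with an SE of 1.19 on the log2 scale, and its call ended without wild-type array 3, 4 or 6 or 15lox/1638N array 1 or 3, where adjusted p lay between 0.0554 and 0.154. Ctnnb1 (0.08), Ccnd1 (-0.04), Myc (0.65) and Apc (0.18 at the probe set used) did not pass.

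There were 2569 called genes, 749 higher and 1820 lower, of which 108 and 270 changed over 2-fold. With wild-type arrays 4 to 6 only there were 631, 195 higher and 436 lower, and 630 of these were also among the 2569. Of the 16 genes chosen by size 15 were past in that fit as well, Slc15a2 being the exception. With sex as a covariate in that fit H2-Aa and F13a1 were also not past. Without 15lox/1638N array 1 the count with all wild-type arrays was 1129 and without array 2 it was 948.

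The list test was past its threshold for 7 of 27 lists in 15lox/1638N cells, and for 0 of them with an estimated correlation. Of 21 Wnt/beta-catenin targets 9 rose and 0 fell (13 and 0 adjusted over the list alone; 7 higher with wild-type arrays 4 to 6), with a median of 0.55 and adjusted p = 2.7e-11, or adjusted p = 0.0869 with an estimated correlation. Apcdd1 rose by 2.16, Bmp4 by 2.12 and Lgr5, a stem cell marker of the intestine, by 0.60. Of 14 dendritic cell and MHC class II genes 8 fell and Irf4 rose (8 and 1 adjusted over the list alone; 5 lower and 0 higher with wild-type arrays 4 to 6, so the call of Irf4 ended there), with a median of -0.97 and adjusted p = 0.00076. Of 14 early lymphoid genes 6 fell and Il7r rose (8 and 1 adjusted over the list alone; 4 lower with wild-type arrays 4 to 6), the former including Ccr9 at -2.87, Ly6d at -2.87, Notch1 at -0.90 and Ighm at -0.97 (list adjusted p = 0.0015). Of 22 interferon response genes 9 fell and 0 rose (11 lower adjusted over the list alone; 0 with wild-type arrays 4 to 6; list adjusted p = 0.0046). Among these Rsad2 fell by 1.47, Oasl2 by 1.16, Ddx58 by 1.04 and Ifit3 by 0.45. None of the 4 passed without 15lox/1638N array 2, where adjusted p was 0.129, 0.125, 0.0862 and 0.0760 in that order; Rsad2 and Oasl2 also missed it without array 1 (0.0573 and 0.0561), as did Ifit3 without array 3 (0.0839).

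Of 21 DNA replication and G1/S genes 3 rose in 15lox/1638N cells (9 adjusted over the list alone; 0 with wild-type arrays 4 to 6; list adjusted p = 1.2e-05). These were Ccne2 (0.75), E2f1 (0.46) and Rrm2 (0.30), and each call ended without 15lox/1638N array 1 or array 2, with adjusted p between 0.0707 and 0.230; that of E2f1 also ended with the mean of its probe sets, and that of Rrm2 without each wild-type array too, with adjusted p from 0.0503 to 0.0762. Of 20 ribosome biogenesis genes Rrs1 rose by 0.39 (5 adjusted over the list alone; 0 with wild-type arrays 4 to 6; list adjusted p = 2.1e-05), a call that ended without wild-type array 2, 3, 5 or 6 or 15lox/1638N array 1 or 2, with adjusted p from 0.0504 to 0.160. Of 20 neutrophil and granulocyte markers 3 rose (3 adjusted over the list alone; 2 with wild-type arrays 4 to 6; list adjusted p = 0.0344), including Ms4a3 by 0.77 and Prtn3 by 0.43. Apart from the Wnt targets, the 6 lists past the test had adjusted p = 0.659 with an estimated correlation. Of the 32 haematopoietic stem cell genes 3 rose and 4 fell (4 and 6 adjusted over the list alone; 1 and 0 with wild-type arrays 4 to 6), with Tek at 2.40 ± 0.27 (SE) and Hoxa9 at -0.33, the latter not past with wild-type arrays 4 to 6. Outside the lists past the test Ebf1, Il2rb, Cd3g and Pmepa1 fell by 2.33, 1.62, 1.44 and 1.16. Of 19 monocyte and macrophage markers 3 rose and 2 fell (3 and 3 adjusted over the list alone; 3 and 0 with wild-type arrays 4 to 6), with a median of -0.18: Cd14, Ccr2 (0.89) and F13a1 (1.23) rose, and Itgam read -0.36, a call that ended without 15lox/1638N array 2 (adjusted p = 0.104) or array 3 (adjusted p = 0.0661). For 3 of the 27 lists, none of them past the test, the median, mean and test differed in sign.

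The 15lox/1572T cells differed from wild type in fewer of the tested genes. Cd14 rose 5.61-fold, from 6.62 ± 0.24 (SD, n = 6) to 9.11 ± 0.20 (SD, n = 3, adjusted p = 9.2e-06), and Pdcd1 5.91-fold, from 6.66 ± 0.63 to 9.22 ± 0.87 (adjusted p = 0.0083). Rasgrp1 rose 4.46-fold, Nrp2, a semaphorin receptor, 3.23-fold, Plpp1 2.97-fold and Pxdc1 2.60-fold. Crispld2 fell by 1.74 ± 0.13 (SE), the BMP-binding protein gene Bmper by 1.97 ± 0.23 and Cracdl by 2.00 ± 0.23. Igha read -3.03 ± 0.62, a call that ended without any 1 of wild-type arrays 1 to 5 or 15lox/1572T arrays 1 and 2 (adjusted p 0.0502 to 0.159). Lef1 (-0.32), Nkd1 (0.11), Ctnnb1 (-0.02), Ccnd1 (-0.15) and Myc (0.24) did not pass. Axin2 read 8.61 ± 0.83 against 7.40 ± 0.38, a log2 fold change of 1.21 that also missed the threshold (adjusted p = 0.0615).

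The count was 197 genes, 41 higher and 156 lower, of which 11 and 39 changed over 2-fold; with wild-type arrays 4 to 6 only it was 20 genes, 5 higher and 15 lower. Of the 16 genes chosen by size, 5 were past the threshold with wild-type arrays 4 to 6: Cd14, Pdcd1, Bmper, Cracdl and Crispld2. With sex as a covariate in that fit 8 genes were called, and Pdcd1 and Cracdl were not among them. With the mean of its probe sets Rasgrp1 was not past the threshold either. Left-out arrays moved the count to 91 without wild-type array 1, 101 without array 2, 120 without array 3, 91 without array 4, 103 without array 5 and 57 without 15lox/1572T array 1.

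**Figure D4:**
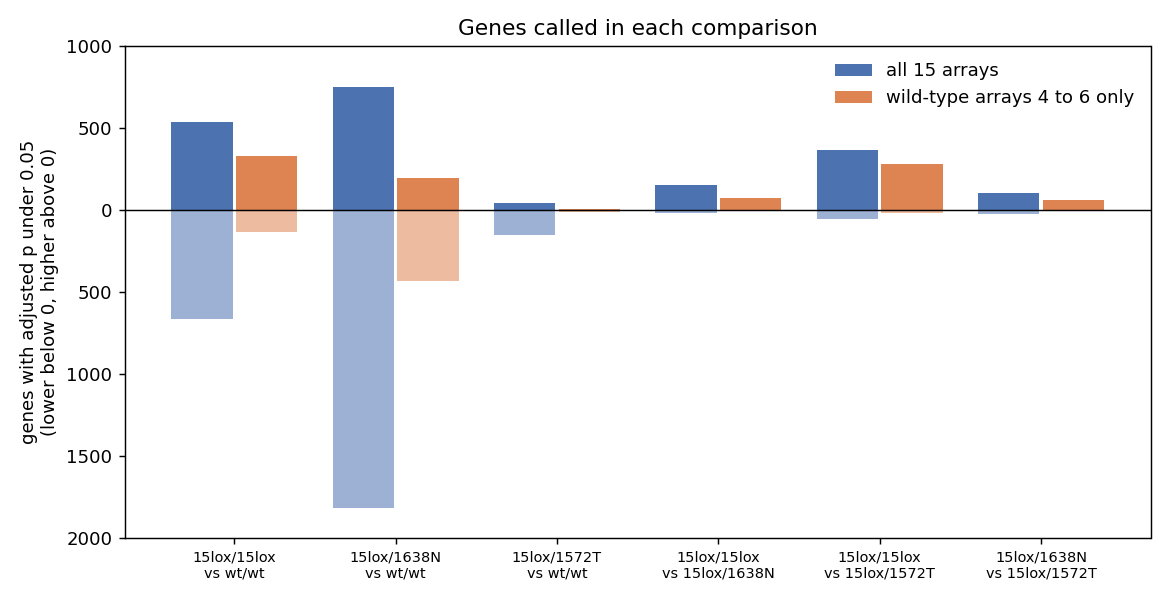
Bars give the number of genes with adjusted p under 0.05 in 6 comparisons, those higher in the first-named genotype above 0 and those lower below 0 in the paler shade, for the fit with all 6 wild-type arrays and that with wild-type arrays 4 to 6 only. The counts fall from 1199 to 464, from 2569 to 631 and from 197 to 20 in the 3 comparisons with wild type.

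The list test was past its threshold for 10 of 27 lists in 15lox/1572T cells, and for 0 with an estimated correlation. In the list of 14 early lymphoid genes Ccr9 fell by 1.83 and Ighm by 0.84 (6 lower and 1 higher adjusted over the list alone; list adjusted p = 0.00037, and adjusted p = 0.611 with an estimated correlation). In the list of 14 dendritic cell and MHC class II genes H2-Eb1 fell by 2.00 and Ciita by 1.44 (6 lower adjusted over the list alone; list adjusted p = 0.0023, and adjusted p = 0.659 with an estimated correlation). All 4 of these calls ended without 15lox/1572T array 1, with adjusted p of 0.0507, 0.0603, 0.0993 and 0.0682 in that order, that of H2-Eb1 ended without array 2 too (0.0739), and with wild-type arrays 4 to 6 neither list had a member past the threshold. Of 15 T cell markers Cd3g was 2.38-fold lower (adjusted p = 0.00059) and Cd3e fell by 0.33 (5 lower adjusted over the list alone; 1 with wild-type arrays 4 to 6; list adjusted p = 0.0039, and adjusted p = 0.319 with an estimated correlation); the call of Cd3e ended without any 1 of 10 arrays, with adjusted p up to 0.175. Hspa1b, an inducible heat shock protein, rose by 1.51 in the list of 15 immediate early and heat shock genes (2 higher adjusted over the list alone; 0 with wild-type arrays 4 to 6; list adjusted p = 0.0042, and adjusted p = 0.0976 with an estimated correlation), a call that ended without 15lox/1572T array 1 (adjusted p = 0.0902).

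The other 6 lists past the test in 15lox/1572T cells had small medians and at most 1 changed member. The 18 mast cell, basophil and eosinophil markers had a median of 0.24 (adjusted p = 0.0023, and 0.319 with an estimated correlation), with Ms4a2 at 1.17 and Hdc at 0.89 not past the threshold. The 16 megakaryocyte markers had a median of 0.19 (adjusted p = 0.0153), the 20 ribosome biogenesis genes one of 0.12 (adjusted p = 0.0072), and the 20 mitosis genes one of -0.10 (adjusted p = 0.0057), with 0 members past the threshold in each; adjusted over the list alone, 3 mitosis genes were lower and 0 members of the other 3 lists differed. The 20 neutrophil markers had a median of 0.04 (adjusted p = 0.0311) with Ms4a3 higher by 0.61 (2 higher adjusted over the list alone; 0 with wild-type arrays 4 to 6), a call that ended without wild-type array 2 (adjusted p = 0.0555) or 15lox/1572T array 1 (adjusted p = 0.117). The 21 Wnt/beta-catenin targets had a median of 0.09 (adjusted p = 0.0344), with 0 members past the threshold and 1 higher adjusted over the list alone. With an estimated correlation these 5 lists had adjusted p of 0.659 to 0.749. For 7 of the 27 lists, none of them past the test, the median, mean and test differed in sign. The median log2 fold change of plasmacytoid dendritic cell markers, a list chosen after the data were seen, was -0.58 in 15lox/15lox, -0.77 in 15lox/1638N and -0.50 in 15lox/1572T cells.

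**Figure D5:**
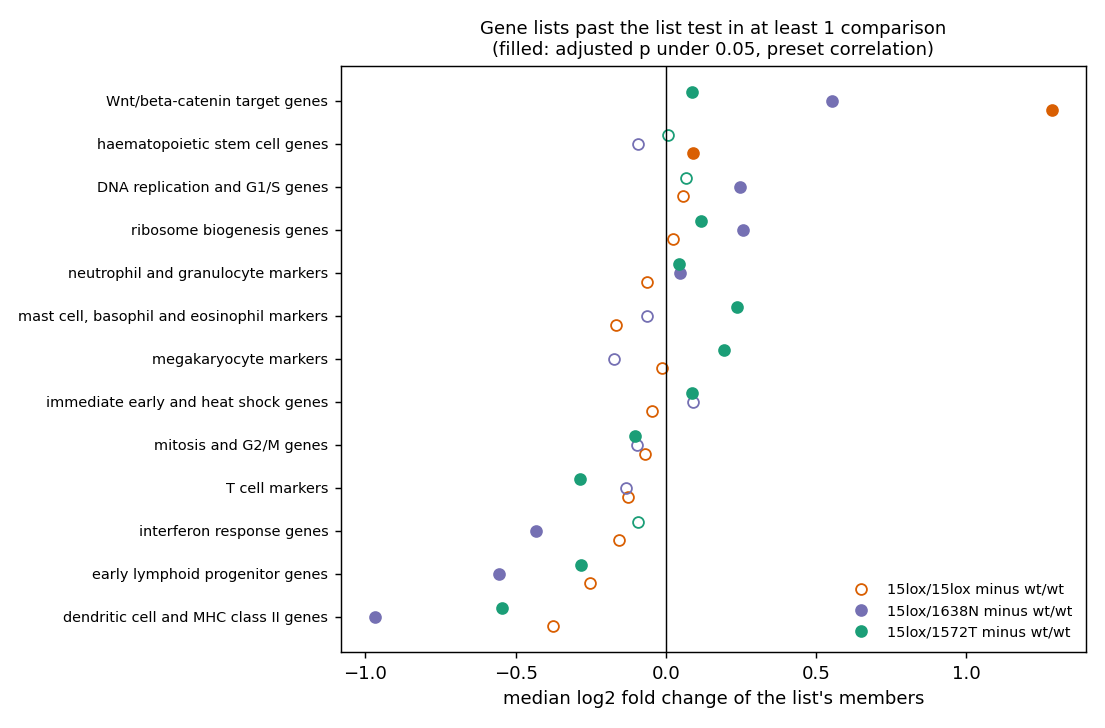
Points give the median log2 fold change against wild type of the members of each gene list past its test in at least 1 comparison, by genotype, and filled points are past adjusted p under 0.05 with the preset correlation. The Wnt/beta-catenin targets lie at 1.29, 0.55 and 0.09 in 15lox/15lox, 15lox/1638N and 15lox/1572T cells.

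The mutant genotypes were then compared directly, since a gene past the threshold in a single genotype is not thereby shown to differ from the others. Between 15lox/15lox and 15lox/1638N cells, Nrep was higher in the former by 2.80 ± 0.23 (SE), Unc45b by 2.72 ± 0.32, Fetub by 2.66 ± 0.27, Ahsg by 2.61 ± 0.33 and Tfcp2l1 by 2.61 ± 0.27. Camk4, a kinase of lymphoid cells, was lower there (-1.65 ± 0.22), as were Fcgr4 (-0.97) and Pla2g4c (-0.89). Cd14 read -1.11, a call that ended without 15lox/1638N array 1 (adjusted p = 0.0765) or array 2 (adjusted p = 0.0520), and Ms4a3 -0.83, which ended without array 2 (adjusted p = 0.0508). Of the 21 Wnt targets 6 were higher in 15lox/15lox cells (10 higher and 3 lower adjusted over the list alone; 4 higher with wild-type arrays 4 to 6; list adjusted p = 0.00014, and adjusted p = 0.404 with an estimated correlation), among them, named after their values were seen, Bmp4 by 2.36, Tnfrsf19 by 1.76, Wif1 by 1.61 and Nkd1 by 1.41, whereas Axin2 (0.91, adjusted p = 0.268) and Lef1 (0.02, adjusted p = 0.985) did not differ past the threshold. There were 172 called genes, 153 higher in 15lox/15lox and 19 lower, and 76 (71 and 5) with wild-type arrays 4 to 6 in the fit. The count was 77 without 15lox/1638N array 1, 69 without array 2, 378 without array 3 and 105 without 15lox/15lox array 3. With only the 6 arrays of these genotypes in the fit it was 2, and the 10 genes named first in this paragraph, Nrep to Ms4a3, were not past the threshold. At most 2 of the 6 Wnt targets can therefore have kept their call in that fit. Camk4 also missed it with the mean of its probe sets, and Fcgr4 with wild-type arrays 4 to 6 only.

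Against 15lox/1572T cells, 15lox/15lox cells had higher Sult1a1 (6.83 ± 0.36, SE), Edar (6.11 ± 0.24), Ahsg (6.09 ± 0.33), Efhd1 (4.90 ± 0.40) and Phlda1 (4.73 ± 0.34), and lower Kcne3 (-1.77 ± 0.30) and Vpreb1 (-1.18 ± 0.19). Of the Wnt targets 11 were higher (14 higher and 1 lower adjusted over the list alone; 11 higher with wild-type arrays 4 to 6; list adjusted p = 1.5e-19, and adjusted p = 0.0213 with an estimated correlation), including Lef1 by 4.25 and Axin2 by 3.56. There were 423 called genes, 367 higher and 56 lower, and 297 (278 and 19) with wild-type arrays 4 to 6 in the fit. With only the 6 arrays of both genotypes there were 190, without Kcne3 and Vpreb1. Between 15lox/1638N and 15lox/1572T cells, Sult1a1 was higher in the former by 5.52 ± 0.36, Lef1 by 4.23 ± 0.40, Edar by 4.05 ± 0.24, Ahsg by 3.48 ± 0.33 and Zcchc14 by 3.40 ± 0.44, and S100a5 was lower (-1.12 ± 0.16). Kcne3 read -1.80, a call that ended without 15lox/1572T array 1 (adjusted p = 0.0564). Of the Wnt targets 6 were higher (9 adjusted over the list alone; 3 with wild-type arrays 4 to 6; list adjusted p = 9.8e-12, and adjusted p = 0.0763 with an estimated correlation), including Axin2 by 2.65. This comparison called 124 genes, 101 higher and 23 lower, and 64 (60 and 4) with wild-type arrays 4 to 6 in the fit. The count was 66 without 15lox/1572T array 1, 80 without its array 2, 75 without 15lox/1638N array 1, and 16 with only the 6 arrays of both genotypes, where Ahsg, S100a5 and Kcne3 were not past.

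Over all 4 genotypes 1803 genes differed by the F test, and 502 with wild-type arrays 4 to 6 only; the count was 1153 without 15lox/1638N array 1 and 1150 without its array 2. A trend was fitted over the order wild type, 15lox/1572T, 15lox/1638N, 15lox/15lox, an order of the alleles taken from background knowledge and not from the labels. Per step of that order Sult1a1 rose by 2.55 ± 0.24 (SE), Edar by 2.24 ± 0.16, Plpp1 by 2.10 ± 0.12, Rasgrp1 by 2.07 ± 0.12 and Ahsg by 2.05 ± 0.18. These slopes average unequal steps. Sult1a1 read 4.83 to 5.81 in wild type, 5.33 to 6.42 in 15lox/1572T and 10.46 to 11.68 in 15lox/1638N. Edar read 4.40 to 4.85, 4.51 to 5.55 and 8.63 to 9.55 in that order. Plpp1 and Rasgrp1 were called higher in 15lox/1572T with all wild-type arrays. Igha fell per step by 1.27 ± 0.27, Cd7 by 1.20 ± 0.21, Cd74 by 1.01 ± 0.23, Ccr9 by 0.98 ± 0.14 and Ly6d by 0.94 ± 0.18. These 5 did not follow the order at its last step: their log2 fold changes against wild type were further below 0 in 15lox/1638N than in 15lox/15lox, although none of these differences was past the threshold. The trend called 1457 genes, 548 rising and 909 falling, and with wild-type arrays 4 to 6 only 421, 319 rising and 102 falling, so the share rising went from 37.6% to 75.8%. Without 15lox/15lox array 2 there were 817 and without its array 3 there were 2487. Among the falling genes, Igha, Cd74 and Ly6d were not past the threshold with wild-type arrays 4 to 6 (adjusted p = 0.128, 0.173 and 0.0561).

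The log2 fold changes of the mutant genotypes against wild type correlated across genes, which are not independent replicates and here share their controls. Pearson's r was 0.726 between 15lox/15lox and 15lox/1638N, 0.475 between 15lox/15lox and 15lox/1572T, and 0.693 between 15lox/1638N and 15lox/1572T. Unchanged groups simulated against the same controls, with wild-type arrays 1 to 3 shifted as in the data, gave a mean r of 0.497 and 0.496 for the pairs with 15lox/15lox and at most 0.553 for the hypomorphs. The r of 15lox/15lox with 15lox/1572T lay below its simulated mean but cannot be judged by it. The simulated groups hold no changes, and changes in a single genotype lower r. Covariances are not lowered in that way. The covariances were 0.0988, 0.0388 and 0.0568 against simulated values of 0.0146, 0.0146 and 0.0147. With different wild-type arrays for each member of a pair, r ranged over 18 ordered splits, those of arrays 1 to 3 against 4 to 6 left out since their means are the same, from 0.533 to 0.735, from 0.288 to 0.447 and from 0.441 to 0.668. If arrays 1 to 3 were shifted as they look, both sides of each of these splits still carry the mean of arrays 4 to 6. The splits therefore do not remove the shared controls. Of the genes called higher, 287 were shared by 15lox/15lox and 15lox/1638N, including Sult1a1, Edar, Rasgrp1, Plpp1, Lef1 and Axin2, and 436 of those called lower, including Igha, Cd7, Cd74, Ccr9 and Ly6d. Lists of the same lengths, taken by p from 20 simulated sets of unchanged groups with the same shifted controls and each gene drawn independently, shared at most 173 and 328. Simulated lists, here and below, rank noise alone and hold no structure shared by the genes of an array. They therefore give no measure of how far calls are shared beyond the controls. With wild-type arrays 4 to 6 only, 142 genes called higher and 107 called lower were shared. The 15lox/1572T calls shared 27 higher and 97 lower genes with 15lox/15lox (at most 25 and 74 in the simulated sets), and 32 higher and 135 lower genes with 15lox/1638N (at most 27 and 101); with wild-type arrays 4 to 6 only these were 4, 13, 5 and 15. Of the 41 higher and 156 lower genes of 15lox/1572T, 25 and 93 were called in the same direction in both other genotypes, Rasgrp1 and Plpp1 among the former and Igha, Ccr9 and H2-Eb1 among the latter. This overlap was not simulated for the shared controls. None of the genes just named kept its call in 15lox/1572T with wild-type arrays 4 to 6 only.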

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

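The tests of the wild-type sets of 3, of the lymphoid and dendritic genes and of the T lymphocyte genes were chosen only after the result was seen. The list of plasmacytoid dendritic cell markers was added after the data were seen, but its test was written before the values of its markers were seen. The splits of the samples were planned. Among 169 sets of wild-type values tested, 11 held an array far from the other 5, the gap to its nearest neighbour as a share of the range being above Dixon's 95% critical value for 6 samples. Chance gives about 1 in 20, or 8.45. They lay in array 1 (1), array 2 (1), array 3 (3), array 5 (3) and array 6 (3).

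For Birc3 the ratio of gap to range was 0.729, with array 3 at 11.33 and the others at 10.85 to 10.98. For Btrc it was 0.630, with array 6 at 9.80 against 9.36 to 9.52. For Cd83 it was 0.633, with array 3 at 6.64 against 5.55 to 5.95, all below the 15lox/15lox mean of 10.86. For Fcgr4 it was 0.636, with array 5 at 6.41 against 6.27 to 6.32. For Hey2 it was 0.681, with array 1 at 4.04 against 4.09 to 4.11. For Igll1 it was 0.713, with array 6 at 6.60 against 6.25 to 6.35. For Il2rb it was 0.748, with array 5 at 7.32 against 6.68 to 6.84. For Lcn2 it was 0.699, with array 3 at 7.65 against 6.49 to 6.84. For Mecom it was 0.667, with array 5 at 10.06 against 10.30 to 10.42. For Pdgfrb it was 0.727, with array 2 at 11.15 against 11.31 to 11.37. For Sesn1 it was 0.778, with array 6 at 12.11 against 12.02 to 12.04.

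Wild-type arrays 1 to 3 and 4 to 6 had the same mean within 0.05 at 96.7% of probe sets. Repeat arrays of the same RNA are excluded: Xist ranged over 6.26 within arrays 1 to 3 and over 0.234 within arrays 4 to 6. A candidate explanation is a shift of each probe set of arrays 1 to 3 onto the mean of arrays 4 to 6 before deposit, and 10 of the 12 sex-linked values of arrays 1 to 3 lay over 0.5 from every other array, as such a shift needs. What reason there was for it stays open, and no biological explanation was tested.

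Some lymphoid, dendritic and MHC class II genes, among them Ccr9, Ighm, H2-Eb1 and Ciita, were lower in all 3 mutant genotypes, the 4 calls in 15lox/1572T ending without its array 1 (adjusted p = 0.0507 to 0.0993) and with wild-type arrays 4 to 6 only, while Irf4 and Il7r rose in 15lox/15lox and 15lox/1638N (Irf4 in 15lox/1638N not with wild-type arrays 4 to 6 only); neither list passed in 15lox/15lox (adjusted p = 0.0647 each), and with an estimated correlation neither passed in any genotype (adjusted p from 0.611 to 0.659). Fewer cells of plasmacytoid dendritic type could account for part of it: the medians of 11 markers were -0.58, -0.77 and -0.50, the highest being -0.498. All 11 read below 0 in each genotype, against shared controls, but some lay near 0. Klk1 read -0.004, -0.099 and -0.022 and Cd209d -0.033, -0.147 and -0.007, where the median of all genes was -0.046, -0.036 and -0.026. Only 4, 6 and 1 markers were past the threshold as lower. With wild-type arrays 4 to 6 only, these were Pacsin1 and Smim5 in 15lox/15lox, the same with Tlr7 and Lair1 in 15lox/1638N, and Pacsin1 in 15lox/1572T. A difference of the wild-type cultures from all mutant cultures alike would leave 15lox/15lox and 15lox/1638N equal; over the 28 genes of both lists the median difference between them was 0.302, and limma's rotation test fry gave p = 0.0223 on all arrays and up to 0.108 without 1 array, with too few splits for an exact test. The same value of 0.302, higher in 15lox/15lox, goes against the assumed order of the alleles for that pair, but its p with an array left out keeps this open too. These explanations cannot be told apart here, since every mutant culture differs from the wild-type cultures in genotype and in being another culture.

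Of 6 genes known from T lymphocytes, Pdcd1 and Rasgrp1 were past the threshold as higher in all 3 mutant genotypes, Lef1 and Il7r in 15lox/15lox and 15lox/1638N, and Gata3 and Zap70 in 15lox/15lox. With wild-type arrays 4 to 6 the calls of Rasgrp1 in 15lox/1572T (adjusted p = 0.147) and Zap70 (adjusted p = 0.131) ended, as did that of Zap70 without 15lox/15lox array 3 (adjusted p = 0.0670) and that of Rasgrp1 in 15lox/1572T with the mean of its probe sets. The values argue against T cells with CD3 transcripts as the source: the highest log2 fold change of Cd3d, Cd3e and Cd3g over the 3 genotypes was -0.132, and Cd3g read -1.27, -1.44 and -1.25. Whether cells of the T lineage with few CD3 transcripts contributed was not tested. With the Apc genotype as the explanation, 4 of the 6 (Rasgrp1, Lef1, Il7r and Gata3) were past the threshold as higher in 15lox/15lox than in 15lox/1572T. That these 4 genes may follow the loss of Apc function is a hypothesis found and tested on the same data.

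Other splits of the same arrays into groups of the same sizes were counted for each comparison; they treat the wild-type arrays as exchangeable, which the apparent shift of arrays 1 to 3 puts in doubt. For 15lox/15lox against wild type 1 of 84 splits, the real one, gave as many as 1199 genes, and the highest other gave 454. For 15lox/1638N 1 of 84 gave 2569, the highest other 1, and for 15lox/1572T 1 of 84 gave 197, the highest other 5. For the 1803 genes over 4 genotypes it was 1 of 100 (highest other 512) and for the 1457 of the trend 1 of 100 (highest other 0). Chance is excluded as the source of these counts only as far as the wild-type arrays are exchangeable; with wild-type arrays 4 to 6 only, 15lox/1572T had 20 genes, and 3 arrays against 3 have too few splits to test that. For the number of gene lists past the test, chance cannot be excluded for the 2 in 15lox/15lox (74 of 84 splits gave as many, highest other 8) or the 7 in 15lox/1638N (18 of 84, highest other 9). These splits count lists and do not ask how far a single list passed, so they do not test the Wnt/beta-catenin targets by themselves. With camera at the preset correlation that list passed in 29 of 29 alternative fits in 15lox/15lox (adjusted p at most 8.5e-07) and in 15lox/1638N (at most 6.7e-05). With an estimated correlation adjusted p was 0.0129 and 0.0869. For the 10 lists in 15lox/1572T, 3 of 84 splits gave as many. The others, also with 10, set wild-type arrays 1 to 3 or 4 to 6 against the rest. As these sets share a mean, such splits carry the genotype contrast itself, reversed and smaller, and do not measure chance. The 74 and 18 splits above include some of this kind too. With an estimated correlation 0 lists passed in 15lox/1572T, so chance is still not taken as excluded there. Between mutant genotypes 10 splits are too few for a share under 0.05: 15lox/15lox and 15lox/1638N gave 172 with 439 as the highest other (2 splits as large), 15lox/15lox and 15lox/1572T 423 with 5 (1 split), and 15lox/1638N and 15lox/1572T 124 with 2 (1 split). The split that gave 439 set 15lox/15lox arrays 1 and 3 with 15lox/1638N array 3 against the rest, which may point to a structure of the samples; what sets these arrays apart was not tested.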

How the results depend on the processing

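The fits with wild-type arrays 1 to 3 as a group of their own, and with wild-type arrays 4 to 6 only and sex as a covariate, were chosen only after the data were seen. The order below is 15lox/15lox, 15lox/1638N and 15lox/1572T against wild type (1199, 2569 and 197 genes), then 15lox/15lox against 15lox/1638N (172), 15lox/15lox against 15lox/1572T (423), 15lox/1638N against 15lox/1572T (124), the F test (1803) and the trend (1457). Counts within 1.5 times of those, and correlations within 1 SD of the values without 1 array, are left out; they made up 320 of 443 comparisons. The cause was not tested, except that a stricter or looser threshold changes counts by construction. Signal over background and the number of arrays limit precision.

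With wild-type arrays 4 to 6 only the counts were 464, 631 and 20, then 76, 64 (15lox/1638N against 15lox/1572T), 502 and 421. With wild-type arrays 1 to 3 only they were 434, 554 and 20, then 67, 57, 436 and 405. With wild-type arrays 1 to 3 as a group of their own they were 532, 919 and 24, then 114 and 659 (F test), and 1 list in 15lox/15lox. With wild-type arrays 4 to 6 and sex they were 260, 528 and 8, then 52, 254, 67, 332 and 228, and r between 15lox/1638N and 15lox/1572T was 0.725. With the replicate block over the 12 arrays numbered 1 to 3 they were 475, 939 and 29, then 111, 595 (F test) and 401. The 18 same-number pairs had r from -0.130 to 0.430, 7 of them over 0.1, and 7 of 12 arrays correlated best with their own number. Since not every pair was over 0.1 the numbers were not taken as pairs, but the mean r was 0.067 for the same number and -0.033 for different numbers. Among wild type, 15lox/15lox and 15lox/1638N, arrays 2 gave r from 0.120 to 0.333 and arrays 3 from 0.123 to 0.430. Arrays 1 gave -0.130 to -0.052. A factor shared by some of these arrays stays open.

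Without the lowest 50% of genes by mean level the counts were 509 and 95 (15lox/1572T), then 20, 180, 40, 960 and 649, with 7 lists in 15lox/15lox and r of 0.568 (15lox/15lox with 15lox/1572T) and 0.738 (15lox/1638N with 15lox/1572T). Without the lowest 25% 8 lists passed in 15lox/15lox. With an absolute log2 change of at least 1 there were 302, 378 and 50, then 82, 212, 66 and 44 (trend). Against a 1.5-fold change (treat) there were 194, 106 and 2, then 19, 128, 24 and 25. With adjusted p under 0.1 there were 1873, 4070 and 519, then 191 (15lox/1638N against 15lox/1572T), 2969 and 2345. With array weights there were 4473 (15lox/1638N), 408 (15lox/1572T), 3482 and 2952, and r between the hypomorphs was 0.614. With only the arrays of the 2 groups there were 312 (15lox/1572T), 2, 190 and 16. Over all probe sets there were 1951, 3912, 697 (15lox/15lox against 15lox/1572T) and 2457. With 15lox/1572T and 15lox/1638N exchanged in the order the trend called 223.

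For lists, 4 passed in 15lox/15lox with trend and robust options and 8 with the upper 75% of genes as background; with an estimated correlation 1, 0 and 0 passed in the 3 genotypes, and with fry 6 in 15lox/15lox and 4 in 15lox/1572T. With the mean of a gene's probe sets Apc reversed to -2.13, -0.72 and -0.49 and Anxa1 in 15lox/1638N to -0.083. Sizes moved too. Over all alternative fits the log2 fold change in 15lox/15lox was as small as 2.94 for Axin2, 0.82 for Tnfrsf19 and -0.55 for Ebf1. That of Sult1a1 was at least 6.85. Tfcp2l1 differed between 15lox/15lox and 15lox/1638N by as little as 0.79, and the slope of Edar was as small as 1.10. Without each array in turn the counts ranged over 598 to 1456, 948 to 3124 and 57 to 273, then 69 to 378, 337 to 470, 66 to 172, 1150 to 2378 and 817 to 2487; lists over 1 to 5, 5 to 7 and 7 to 11; and r over 0.606 to 0.812 (15lox/15lox with 15lox/1638N), 0.402 to 0.507 (with 15lox/1572T) and 0.601 to 0.710 (between the hypomorphs).

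Of 193 named results past the threshold, 80 were past it in every alternative run. Over 7625 comparisons 6807 kept direction and side of the threshold, 709 lost the call, 105 gained it and 4 reversed. The losses were 96 with wild-type arrays 4 to 6 and sex, 82 with wild-type arrays 1 to 3 only, 73 with arrays 4 to 6 only, 63 with arrays 1 to 3 as a group of their own, 59 with the replicate block, and at most 37 in any other fit. Scaling by quantiles or medians moved no share of genes called higher by over 10 points.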

Other observations

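The lists for the mutant genotypes against each other, the following of gene sets across genotypes and its simulation were chosen only after the result was seen. Of the 227 genes over 2-fold higher in 15lox/15lox than in wild-type cells, 223 had a positive log2 fold change in 15lox/1638N and 144 in 15lox/1572T, with medians of 1.72, 0.91 and 0.11 in the 3 genotypes. Of the 75 genes over 2-fold lower, 75 and 73 were negative in the other genotypes, with medians of -1.30, -1.53 and -1.05. The genes were chosen on 15lox/15lox, so its own median is raised by the choice, and the control arrays are shared. In 20 simulated sets of unchanged groups with the same shifted controls, at most 201 and 204 of the 227 highest genes, and at most 70 and 70 of the 75 lowest, had the same sign in the other 2 groups. The mean was 194 for the highest genes in either group. The simulated genes were extreme through noise alone, part of it from the shared controls, whereas the 227 genes rose by a median of 1.72. The simulated counts therefore give no measure by which to judge the 223, 144, 75 and 73. Of 9 housekeeping genes 0 changed in 15lox/15lox and 15lox/1572T, and 1, Gusb, rose by 0.40 in 15lox/1638N, with 0 past the threshold there with wild-type arrays 4 to 6.

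Ahsg and Fetub, plasma proteins usually made by liver, were higher in 15lox/15lox than in 15lox/1638N by 2.61 and 2.66, and so were Unc45b, a myosin chaperone of muscle, by 2.72, and Tfcp2l1, a transcription factor of kidney epithelium and pluripotent cells, by 2.61. These 4 genes were chosen by size and are no tested group, and none was past the threshold with only the 6 arrays of these genotypes in the fit. Between the mutant genotypes, 9 of 27 lists passed for 15lox/15lox against 15lox/1638N, 4 for 15lox/15lox against 15lox/1572T and 8 for 15lox/1638N against 15lox/1572T, and 0, 1 and 0 with an estimated correlation. The mast cell, basophil and eosinophil markers had a median of -0.37 in 15lox/15lox against 15lox/1572T (adjusted p = 0.00093, and adjusted p = 0.207 with an estimated correlation).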
